A study of Homo sapiens with 9 samples.

How the data were processed

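RNA was measured by sequencing in MCF-10A, a non-tumorigenic human breast epithelial cell line, in 3 genotypes with 3 libraries each: the parental line (WT) and knock-in lines carrying the E545K or the H1047R change in PIK3CA, the gene of the catalytic p110-alpha subunit of PI 3-kinase. Per the labels' protocols, the parental line was kept with 20 ng/ml epidermal growth factor (EGF) and the knock-in lines without it (0 ng/ml), in medium with 5% horse serum. All cells spent the last 24 h before harvest in assay medium with 0.2 ng/ml EGF and 1% charcoal-stripped serum. Ribosomal RNA was depleted, and paired 150 bp reads were made, per the labels' protocols.

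The values are deposited gene counts in 2 tables, and per the file headers both were made by featureCounts 2.0.0 with the GENCODE 32 annotation of the hg38 genome. Reads overlapping several genes were counted for each of them, exons were the counted features, strand was not used and each of the 2 mates of a pair was counted by itself, per the file headers. The submitters' processing notes also name Trim Galore 0.4.0, cutadapt, FastQC, STAR and SAMtools 1.5, without their settings. The WT and E545K libraries stand in one table and the H1047R libraries in the other, so the table and the genotype H1047R cannot be told apart. Unstranded counting with shared exons means that overlapping and antisense genes share reads, and values of genes with shared exons are uncertain to that extent. Copies of multigene families that share reads are uncertain too.

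The tables hold 60609 genes. Of these, 60295 identifiers were matched without their version number to GENCODE 44 names and 314 were not, and these include 1 member of the gene lists, SOD2. Every count column was used. Total counts were 136132315, 96045875 and 95091894 in WT, 134245702, 102971299 and 95533991 in E545K, and 377093507, 605972919 and 518112601 in H1047R. A count of 0 allows up to 3 counts, which is 0.0220 to 0.0316 CPM (counts scaled to the library total) in WT and E545K libraries and 0.00495 to 0.00796 in H1047R. These floors cover counting error only, because reads carry no molecular identifiers. Between replicate libraries, the variance of counts of genes with at least 100 counts was 2.74 to 3.42 times the Poisson value in WT and E545K and 20.9 to 39.4 times in H1047R, so no pair of libraries agreed within Poisson noise. Counting each mate by itself and reads for every overlapping gene also raises this ratio, which does not show whether libraries came from separate cultures.

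Differences were tested with edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with filterByExpr at its defaults, TMM scaling, 1 quasi-likelihood model of genotype over all 9 libraries and Benjamini-Hochberg adjustment over the 26412 genes tested. A gene was called at an adjusted p under 0.05, and a second count took calls of at least 2-fold. Levels are CPM of the TMM-scaled library size, as mean ± SD of 3 libraries, unless stated otherwise. Log2 fold changes are given ± an approximate standard error, their size divided by the square root of the quasi-likelihood F statistic. It can be too small for genes near the floor in a group. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The pooled biological coefficient of variation was 0.118, against 0.0328 within WT, 0.0286 within E545K and 0.216 within H1047R, so the pooled model is conservative for E545K against WT and lenient for comparisons with H1047R.

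The 25 gene lists were PI3K-AKT-mTOR pathway components, FOXO targets, EGFR-family receptors and ligands, ERK-response and feedback genes, AP-1 and CREB family transcription factors, cholesterol synthesis, fatty acid synthesis, glycolysis, ATF4 and amino acid response, cell cycle, p53 targets, hypoxia targets, mesenchymal genes, epithelial junction genes, basal genes, luminal genes, squamous differentiation genes, interferon response, NF-kB and cytokine genes, matrix proteases, YAP-TEAD targets, TGF-beta response, replication-dependent histones, mitochondrially encoded mRNAs and cytosolic ribosomal proteins. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over 75 tests. Camera with an estimated correlation and fry were the alternatives. With the preset correlation 36 of the 75 tests passed, and with the estimated correlation 0 did, beside 56 by fry, which tests whether a list's genes move one way and does not compare them with other genes. Some lists share members.

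Genotypes, tests, lists, markers of other cell types and the rule for named genes were chosen before the data were examined. The rule took PIK3CA, the 10 largest rises and 10 largest falls per comparison among calls of at least 2-fold without overlap between libraries and with at least 10 CPM in the higher group, up to 3 members of each list plus 1 that went the other way, up to 5 genes for each combination of directions in the 2 knock-in lines, and AKT1, EGFR, AREG, MYC and CCND1. Some genes that the rule took are not reported here. Other genes that make up a count of 5 or fewer, or that are singled out, were chosen after their values were seen. They are TK1, FOXM1, ELK3, RHBDF1, ERBB2, PCNA, ETV4, SPRR1B, SPRY1, IL32, IL1A, TNFAIP2, KRT1, KRT10, S100A9, IVL and FLG, the members given with a count of 5 or fewer, the cell type markers and the genes of WT replicate 1. Genes at 3 counts or fewer in a group are given without a fold change.

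Chromosomes and 10 Mb windows were described by the median log2 fold change of 16279 genes with a mean of at least 1 CPM, with 10000 permutations of genes. Comparisons that share the WT libraries were set beside 20 simulations of unchanged groups against those libraries and beside the overlap of independent lists. The test was tried on simulated counts of 16034 genes. Of 50 genes changed at each size, it recovered 70.0%, 86.0%, 92.0% and 100% at 1.25, 1.5, 2 and 4-fold in E545K against WT, and called 8 of 15834 unchanged genes. In H1047R against WT it recovered 60.0%, 96.0%, 98.0% and 100%, and called 10 of 15834. Every group was simulated with the pooled spread, and only for genes of at least 1 CPM in WT. The trial therefore does not show how the test behaves at the wider spread within H1047R or for lower genes.

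Alternatives were other scalings (RLE, upper-quartile, library totals only), no low-count filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a log2 fold change of 0.5, only the 6 libraries compared, small RNA, histone and mitochondrial genes left out, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a correction for GC content and length, H1047R thinned to the depth of the other groups, protein-coding genes only, leaving out genes at 0 to 60 Mb of chromosome 7, and upper-quartile scaling for the lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and permutations.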

Results

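RNA was sequenced from MCF-10A cells with 3 genotypes of PIK3CA, namely the parental line (WT), a line with the helical-domain change E545K and a line with the kinase-domain change H1047R, with 3 libraries each. MCF-10A is a non-tumorigenic breast epithelial line, and the knock-in lines share its origin. The study set out to compare the transcription of isogenic cells with either change. Total gene counts ranged from 95091894 to 136132315 in WT, from 95533991 to 134245702 in E545K and from 377093507 to 605972919 in H1047R, and each mate of a read pair was counted. A mean of 15986, 16274 and 16256 genes reached 1 CPM in WT, E545K and H1047R. Genes with any count numbered 38163, 39049 and 36770 on average, so H1047R did not hold more of them despite its larger totals.

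The H1047R libraries stood apart in makeup as well as depth. Protein-coding genes took 86.0% ± 0.0519 of counts in WT, 85.5% ± 0.321 in E545K and 77.8% ± 0.246 in H1047R (SD, n = 3). Genes annotated as miscellaneous RNA took 4.71%, 4.71% and 8.76%, and the 20 most abundant genes took 17.1%, 16.1% and 24.3%. The first principal component held 69.0% of the variance and the second 25.7%. Correlations of log2 CPM across genes were 0.943 to 0.952 between H1047R and WT libraries and 0.978 to 0.979 between E545K and WT libraries. Spread between replicates was also larger in H1047R, with a coefficient of variation of 0.216 against 0.0328 in WT and 0.0286 in E545K.

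PIK3CA itself (ENSG00000121879.5, chromosome 3, 179148114 to 179240093, plus strand, hg38) was present in every library. Its level was 43.9, 46.5 and 47.9 CPM in WT, 39.1, 37.7 and 37.4 in E545K, and 42.4, 43.9 and 41.7 in H1047R. It fell by 0.28 ± 0.04 on the log2 scale in E545K against WT (edgeR adjusted p = 1.7e-04). In H1047R against WT the change was −0.11 ± 0.04 (adjusted p = 0.044). That call was lost without WT replicate 2 (−0.11, adjusted p = 0.128), WT replicate 3 (−0.08, 0.200), E545K replicate 1 (−0.11, 0.0578), 2 (−0.11, 0.0705) or 3 (−0.11, 0.0689), or H1047R replicate 1 (−0.10, 0.0542) or 3 (−0.09, 0.0852). It was also lost with the stricter low-count filter (−0.07, 0.124) and with the replicate block (−0.11, 0.0653). Overlapping genes share 35.2% of its exon bases, and gene counts do not show which allele a read came from.

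**Figure D1:**
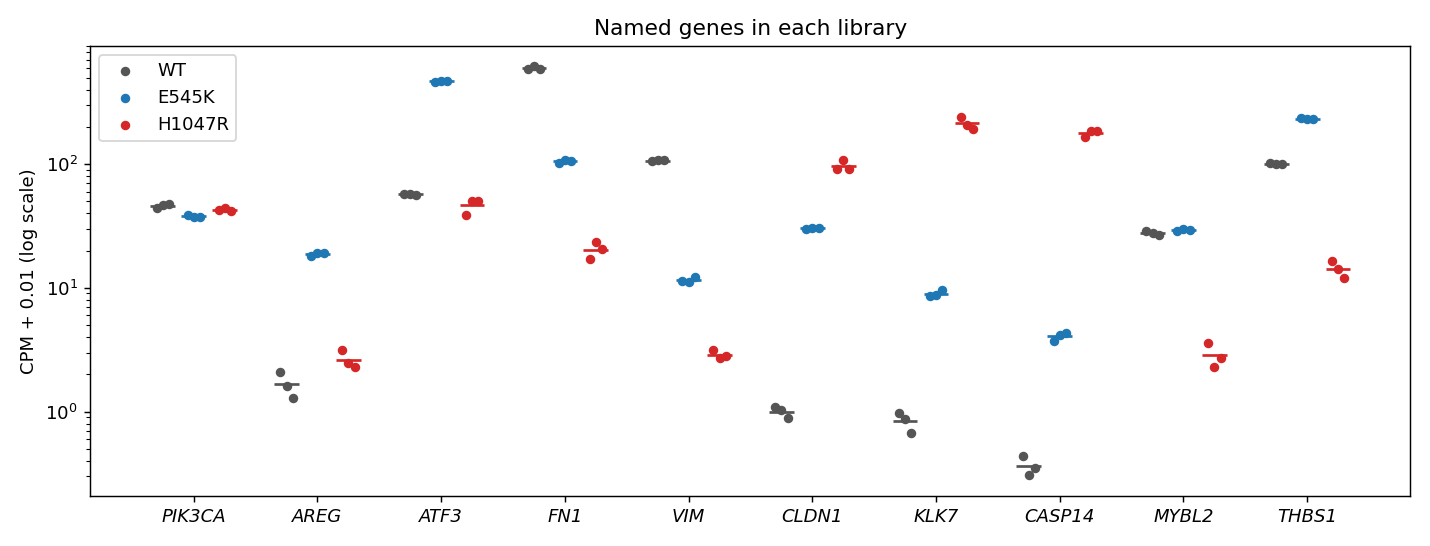
CPM + 0.01 on a log axis for 10 named genes, with 1 point per library and a line at the mean of each genotype (n = 3). CASP14 lay at 0.355 CPM in WT, 4.05 in E545K and 178 in H1047R, and AREG was highest in E545K at 18.7 CPM.

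E545K cells were compared with WT to show what accompanied the helical-domain change. The WT line had been kept with EGF and the knock-in lines without it until the last 24 h, so culture history moves with genotype in both comparisons with WT. The lists of ERK-response genes and p53 targets were higher in E545K by camera, with adjusted p = 0.218 and 0.339 with an estimated correlation, and fibronectin and vimentin RNA fell. Amphiregulin (AREG, ENSG00000109321.11, chromosome 4, 74445136 to 74455005), an EGFR ligand, rose from 1.65 ± 0.415 to 18.7 ± 0.649 CPM (SD, n = 3, log2 fold change 3.47 ± 0.15, adjusted p = 1.81e-10). The stress-response factor ATF3 (ENSG00000162772.17, chromosome 1, 212565334 to 212620777) rose from 56.9 ± 0.478 to 466 ± 5.09 CPM (3.04 ± 0.08, adjusted p = 1.33e-12). Fibronectin (FN1, ENSG00000115414.19, chromosome 2, 215360440 to 215436073) fell from 599 ± 14.6 to 106 ± 2.68 CPM (−2.50 ± 0.08, adjusted p = 9.38e-12), and vimentin (VIM), of which 24.3% of exon bases are shared, from 107 to 11.6 CPM (−3.20 ± 0.06).

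Of the 26412 genes tested, 9663 were called in E545K against WT, with 4665 higher and 4998 lower. With library totals as the only scaling, 66.1% of calls were higher, against 48.3% with TMM, and the median of all genes was 0.10. At least 2-fold, 1193 rose and 682 fell. Without WT replicate 1, a library weighed in the closing section, the counts were 8093 and, at least 2-fold, 1703, of which 1514 were among the 1875 of the full set.

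The tight-junction gene CLDN1 rose by 4.93 ± 0.09 and POF1B by 4.19 ± 0.12. The non-muscle myosin heavy chain MYH14 rose from 0.489 to 17.8 CPM (5.05 ± 0.29, or 6.18 without WT replicate 1, which held 0.981 CPM against 0.233 and 0.255 in the other WT libraries), and the nuclear receptor NR4A3 from 0.453 to 11.5 CPM. The largest rises also held 5 protocadherin-alpha genes (PCDHA12, PCDHA11, PCDHA10, PCDHA6 and PCDHAC1), which share 36.7% to 63.7% of their exon bases with other genes and are uncertain one by one. Among the largest falls, the scaffold gene AKAP12 fell by 3.14 ± 0.04, decorin (DCN) by 2.60 ± 0.09, MYL9 by 2.66 ± 0.11 and EEF1A2 by 4.02 ± 0.18. MT1L, a metallothionein copy that can share reads with its relatives, went from 16.2 to 0.244 CPM, and ONECUT3 from 10.3 to 0.0654 CPM (−7.41 ± 0.24, or −8.14 without E545K replicate 3).

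Of 32 ERK-response and feedback genes, 27 rose and 2 fell (28 and 2 adjusted over the list alone), with a median log2 fold change of 0.94 (camera adjusted p = 4.67e-14, and adjusted p = 0.218 with an estimated correlation). The phosphatase DUSP6 rose by 3.17 ± 0.15, EGR3 by 3.08 ± 0.10 and EGR2 by 2.85 ± 0.11, while SRF fell by 0.44 ± 0.04 and ELK3 by 0.16. Among 19 EGFR-family receptors and ligands, 9 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.20, camera adjusted p = 9.92e-03, and adjusted p = 0.339 with an estimated correlation). HBEGF rose by 2.18 ± 0.09 and NRG4 by 2.10 ± 0.08 beside AREG, and ERBB3 fell by 0.79 ± 0.04, ERBB2 by 0.29 and RHBDF1 by 0.26. EGFR rose from 734 ± 3.49 to 1030 ± 3.21 CPM (0.49 ± 0.04) and lies in the part of chromosome 7 described with the chromosomes.

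Of 24 p53 target genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 2.81e-10, and adjusted p = 0.339 with an estimated correlation). TIGAR rose by 1.46 ± 0.06, AEN by 0.91 ± 0.06, and MDM2, the ubiquitin ligase that opposes p53, from 148 to 302 CPM. The 1 fall, of PHLDA3, was −0.12 and was not called without WT replicate 1 (−0.13, adjusted p = 0.0686), 2 (−0.10, 0.177) or 3 (−0.13, 0.0620), or E545K replicate 1 (−0.11, 0.127), 2 (−0.12, 0.0849) or 3 (−0.13, 0.0793). Of 50 cell cycle genes, 33 rose and 3 fell (36 and 3 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 4.69e-07, and adjusted p = 0.520 with an estimated correlation). NDC80 rose by 1.01 ± 0.15, MCM10 by 0.90 ± 0.12 and CDC6 by 0.85 ± 0.11, and CDT1 fell by 0.66 ± 0.07, FOXM1 by 0.34 and TK1 by 0.26. Of 30 ATF4 and amino acid response genes, 19 rose and 7 fell (20 and 7 adjusted over the list alone, median 0.28, camera adjusted p = 2.28e-03, and adjusted p = 0.621 with an estimated correlation). CHAC1 rose by 2.17 ± 0.18 and the serine synthesis gene PSAT1 by 1.56 ± 0.07, and DDIT4 fell from 508 to 174 CPM.

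Fold changes in this comparison fell with GC content (Spearman correlation −0.225). No list was tested after a correction for GC content, so small list medians may hold part of that trend. Falls led in 6 of the lists called. Of 54 cytosolic ribosomal protein genes, 0 rose and 28 fell (0 and 29 adjusted over the list alone), by small amounts with a median of −0.17 (camera adjusted p = 8.60e-06, and adjusted p = 0.640 with an estimated correlation). RPL37 fell by 0.45 ± 0.08 and RPS15 by 0.28 ± 0.04. Among 25 YAP-TEAD targets, 5 rose and 14 fell (5 and 14 adjusted over the list alone, median −0.13, camera adjusted p = 4.31e-03, and adjusted p = 0.481 with an estimated correlation). The receptor kinase AXL fell by 1.45 ± 0.04, GADD45B by 1.35 ± 0.06 and NUAK2 by 0.99 ± 0.07, whereas the classical targets CCN1 and CCN2 rose by 0.72 and 0.46, beside IGFBP3 at 0.97, F3 at 0.72 and ANKRD1 at 1.07 (not called without E545K replicate 3, 0.97, adjusted p = 0.0517). Of 39 epithelial junction genes, 9 rose and 22 fell (9 and 23 adjusted over the list alone, median −0.22, camera adjusted p = 9.53e-03, and adjusted p = 0.571 with an estimated correlation). EPCAM fell by 0.88 ± 0.08, against the rise of CLDN1. The mean of the list was near 0, and fry gave an adjusted p of 0.0709.

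Of 28 matrix proteases and inhibitors, 7 rose and 14 fell (7 and 15 adjusted over the list alone, median −0.47, camera adjusted p = 0.0297, and adjusted p = 0.530 with an estimated correlation), with falls of MMP2 (−2.58 ± 0.31), CTSV (−1.59 ± 0.12) and ADAM19 (−1.54 ± 0.05). Of 29 basal genes, 7 rose and 17 fell (8 and 19 adjusted over the list alone, median −0.21, camera adjusted p = 0.0282, and adjusted p = 0.520 with an estimated correlation). KRT14 fell by 0.79 ± 0.09 and CNN2 by 0.70 ± 0.05, and the list's call was lost without WT replicate 3 (adjusted p = 0.0563), E545K replicate 1 (0.0605) or E545K replicate 2 (0.0509). Of 35 mesenchymal genes, 7 rose and 14 fell (8 and 14 adjusted over the list alone, median −0.07, or 0.03 with library totals only, camera adjusted p = 0.0439, and adjusted p = 0.571 with an estimated correlation). INHBA fell by 2.56 ± 0.17 beside FN1 and VIM, and thrombospondin 1 (THBS1) rose by 1.21 ± 0.08. That call was lost without E545K replicate 3 (adjusted p = 0.0631) or H1047R replicate 3 (0.0745), with upper-quartile scaling (0.0501) and with the replicate block (0.0598).

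The remaining 14 lists were not called in E545K against WT. Of 36 PI3K-AKT-mTOR pathway components, 9 rose and 18 fell (9 and 20 adjusted over the list alone, camera adjusted p = 0.273), with AKT1 at −0.30 ± 0.04. Of 23 FOXO targets, 5 rose and 10 fell (5 and 12 adjusted over the list alone, adjusted p = 0.0544). SESN3 rose by 1.75 ± 0.05, PDK4 by 0.77, TRIB2 by 0.52, KLF6 by 0.21 and SESN1 by 0.21, TXNIP fell by 1.27 ± 0.04, and the list passed without WT replicate 2 (0.0487) or E545K replicate 3 (0.0427). Of 24 AP-1 and CREB family factors, 13 rose and 6 fell (13 and 7 adjusted over the list alone, adjusted p = 0.114), with FOSL1 up by 2.70 ± 0.08 and FOS down by 1.26 ± 0.04. Of 31 NF-kB and cytokine genes, 16 rose and 7 fell (17 and 7 adjusted over the list alone, adjusted p = 0.0704), with PTGS2 up by 2.57 ± 0.11 and TNFAIP3 by 2.16 ± 0.05. Of 39 squamous differentiation genes, 15 rose and 10 fell (16 and 11 adjusted over the list alone, adjusted p = 0.0706), and the list passed without E545K replicate 1 (0.0375).

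Cholesterol synthesis had 3 rises (FDPS 0.39, HSD17B7 0.20, PMVK 0.18) and 10 falls among 25 genes (3 and 11 adjusted over the list alone, adjusted p = 0.0706), and passed without H1047R replicate 1 (3.08e-03) and with upper-quartile scaling (0.0462). Fatty acid synthesis had 7 rises and 5 falls among 22 genes, with the same counts over the list alone (adjusted p = 0.685), the falls being LPIN1, FADS3, MID1IP1, ACSS2 and ELOVL1. Glycolysis had 4 rises (ALDOC, HK2, LDHA and PGAM1) and 8 falls among 24 genes (5 and 9 adjusted over the list alone, adjusted p = 0.319), and hypoxia targets 4 rises (ANGPTL4, ANKRD37, AK4 and P4HA2) and 8 falls among 21 (4 and 9 adjusted over the list alone, adjusted p = 0.225). Interferon response genes had 18 rises and 10 falls among 47 (19 and 11 adjusted over the list alone, adjusted p = 0.121), and histones 18 and 8 among 44 (18 and 9 adjusted over the list alone, adjusted p = 0.320). Of 32 luminal genes, 9 rose and 13 fell, as over the list alone, and the median of −0.03 differed in sign from the mean of 0.13 and from the test (adjusted p = 0.974). Among these falls, TFF1 (−3.01) and PRLR (−2.32) were at −0.40 and −0.56 and not called without WT replicate 1. TGF-beta response genes had 7 rises and 7 falls among 24, as over the list alone, with a median of −0.04 and a test in the other direction (adjusted p = 0.878). Among 13 mitochondrially encoded mRNAs only MT-ND1 fell (−0.39), as over the list alone (adjusted p = 0.752). With library totals only, the medians of the glycolysis, hypoxia, luminal, TGF-beta and mitochondrial lists lay above 0, at 0.02 to 0.09.

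**Figure D2:**
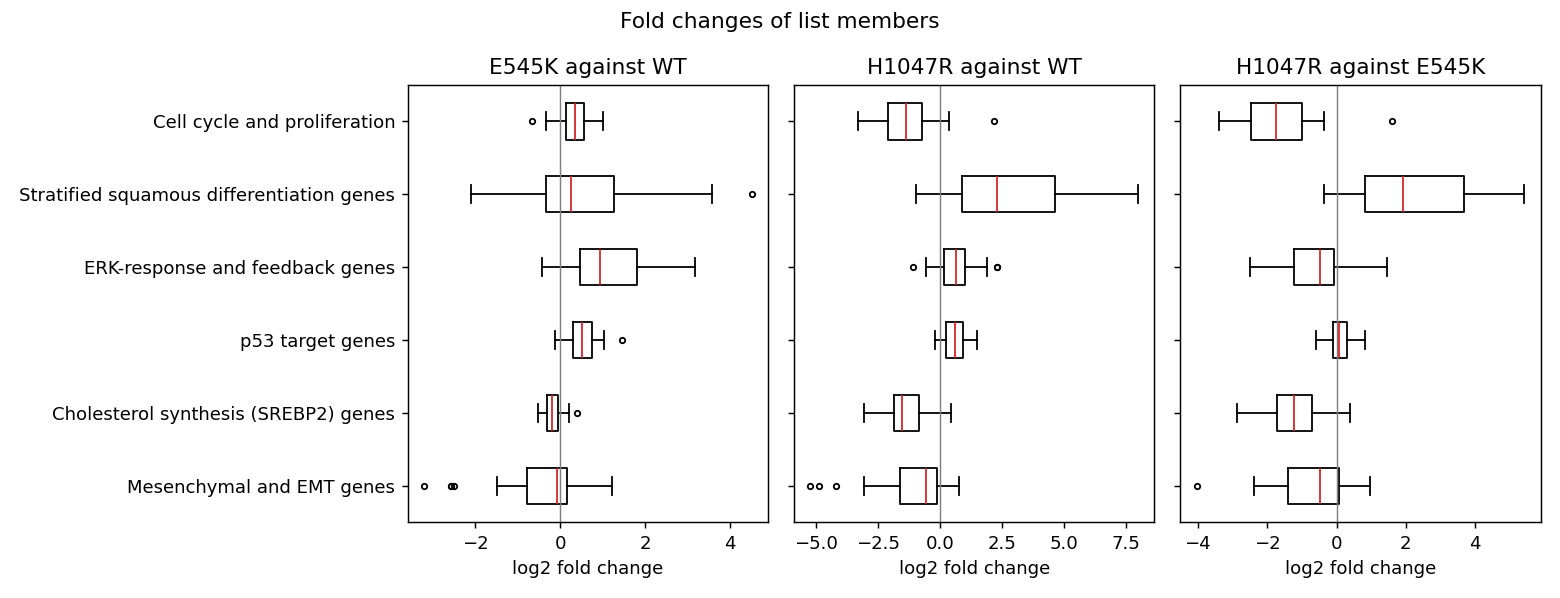
Log2 fold changes of the members of 6 gene lists in the 3 comparisons, without genes at or under 3 counts in any group; boxes span the quartiles, red lines are medians, whiskers reach 1.5 times the interquartile range and circles lie beyond them, and each panel has its own axis. Over all members tested, the cell cycle medians were 0.35, −1.38 and −1.75 and the squamous medians 0.24, 3.24 and 1.97, and leaving out low-count members lowers the squamous box in the middle panel.

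H1047R cells were compared with WT to show what accompanied the kinase-domain change. By camera, the list of squamous (cornifying) differentiation genes was higher in H1047R and those of the cell cycle, cholesterol synthesis and the mesenchymal state were lower. With an estimated correlation these 4 had adjusted p = 0.218, 0.440, 0.489 and 0.339. The skin protease kallikrein 7 (KLK7, ENSG00000169035.12, chromosome 19, 50976468 to 50984099) rose from 0.83 ± 0.157 to 214 ± 25.5 CPM (SD, n = 3, log2 fold change 7.98 ± 0.12, adjusted p = 7.66e-16). The epidermal protease CASP14 (ENSG00000105141.6, chromosome 19, 15049480 to 15058293) rose from 0.355 ± 0.0689 to 178 ± 12.3 CPM (8.93 ± 0.10, adjusted p = 8.72e-17). The cell cycle transcription factor MYBL2 (ENSG00000101057.16, chromosome 20, 43667019 to 43716495) fell from 27.7 ± 0.932 to 2.85 ± 0.635 CPM (−3.30 ± 0.11, adjusted p = 3.75e-12).

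Of 26412 genes, 14651 were called in H1047R against WT, with 7234 higher and 7417 lower, and at least 2-fold 2652 rose and 1951 fell. On protein-coding genes alone the latter split turned to 1273 and 1335, and without a low-count filter to 3196 and 3303. Without WT replicate 1 the counts were 13077 and, at least 2-fold, 4241, of which 3896 were among the 4603 of the full set. The H1047R libraries had larger total counts, held more miscellaneous RNA (8.76% against 4.71%) and came from a separate table, so genotype and table cannot be told apart in any list that follows.

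Other large rises were S100A8 (7.24 ± 0.12), KLK5 (6.70 ± 0.14), CLDN1 (6.61 ± 0.09), KLK10 (6.23 ± 0.20), ATP13A4 (8.98 ± 0.19), AZGP1 (6.96 ± 0.19), and IGFL1 (5.76 ± 0.18), and the mucin MUC16 went from 0.772 to 37.8 CPM. Cyclin D2 (CCND2) fell from 165 ± 1.86 to 1.68 ± 0.318 CPM (−6.63 ± 0.10), the imprinted RNA H19 from 22.9 to 0.399 CPM, and RYR1 from 17.5 to 0.0596 CPM. FN1 fell by 4.88 ± 0.09, VIM by 5.22 ± 0.06, AKAP12 by 5.70 ± 0.05 and EEF1A2 by 8.69 ± 0.23 (−9.35 without H1047R replicate 1). Cyclin D1 (CCND1) rose from 66.6 to 131 CPM (0.98 ± 0.07). EGFR was at 738 CPM in H1047R and 734 in WT (0.01 ± 0.04, adjusted p = 0.850), MYC fell by 0.38 ± 0.05 and AREG rose by 0.63 ± 0.15.

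Of 39 squamous differentiation genes, 33 rose and 3 fell (34 and 3 adjusted over the list alone), with a median of 3.24, or 2.75 with 2 members at or under 3 counts set at their bound (camera adjusted p = 5.90e-12, and adjusted p = 0.218 with an estimated correlation). The keratins KRT1 (4.88) and KRT10 (4.12), S100A9 (5.41), PI3 (4.65), involucrin (IVL, 1.45) and filaggrin (FLG, 1.16) were among them, whereas SERPINB3 fell by 0.97 ± 0.20, KRT80 by 0.96 and SPRR1B by 0.34. Of 50 cell cycle genes, 2 rose and 43 fell (3 and 43 adjusted over the list alone), with a median of −1.38 (camera adjusted p = 3.30e-14, and adjusted p = 0.440 with an estimated correlation). CDC20 fell from 28.3 to 3.17 CPM and BIRC5 by 3.01 ± 0.13, while E2F2 rose by 2.17 ± 0.14 and PCNA by 0.38. Of 25 cholesterol synthesis genes, 1 rose and 24 fell (1 and 24 adjusted over the list alone), with a median of −1.54 (camera adjusted p = 4.10e-10, and adjusted p = 0.489 with an estimated correlation). INSIG1 fell from 114 to 14.6 CPM and HMGCS1, with 37.7% of its exon bases shared, from 316 to 39.7.

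Of 35 mesenchymal genes, 5 rose and 24 fell (5 and 25 adjusted over the list alone), with a median of −0.55 (camera adjusted p = 8.60e-06, and adjusted p = 0.339 with an estimated correlation). INHBA fell by 4.18 ± 0.17 and THBS1 by 2.83 ± 0.08. The rises were TNC (0.63), CD44 (0.45), COL5A2 (0.33), COL12A1 (0.30) and SNAI1 (0.77), the last not called without WT replicate 2 (0.71, adjusted p = 0.0596), WT replicate 3 (0.71, 0.0592) or H1047R replicate 1 (0.65, 0.0524). Of 24 p53 targets, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 3.76e-08, and adjusted p = 0.403 with an estimated correlation). TIGAR rose by 1.51 ± 0.06, TP53INP1 by 1.33 ± 0.05 and MDM2 by 1.31 ± 0.04, and TP53I3 fell by 0.20. Of 31 NF-kB and cytokine genes, 22 rose and 5 fell (22 and 5 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 1.04e-04, and adjusted p = 0.339 with an estimated correlation). Serum amyloid genes SAA1 and SAA2, near copies that can share reads, rose by 3.13 ± 0.08 and 4.52 ± 0.13, and CSF3 (−4.96 ± 0.50, or −5.84 without H1047R replicate 3), IL1B (−4.68), TNFAIP2 (−1.26), IL1A (−1.07) and IL32 (−0.90) fell.

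Of 47 interferon response genes, 29 rose and 7 fell (29 and 7 adjusted over the list alone, median 0.47, camera adjusted p = 2.27e-04, and adjusted p = 0.520 with an estimated correlation). IFI44L rose by 2.75 ± 0.13 and IFI44 by 2.73 ± 0.15, and GBP1 fell by 1.60 ± 0.05. Of 32 ERK-response genes, 24 rose and 4 fell (24 and 4 adjusted over the list alone, median 0.66, camera adjusted p = 2.32e-04, and adjusted p = 0.385 with an estimated correlation). ETV5 rose by 2.31 ± 0.24, the ephrin receptor EPHA4 by 2.30 ± 0.07 and DUSP6 by 1.90 ± 0.15, and the falls were SRF (−1.10 ± 0.04), ETV4 (−0.56), MYC and ELK3 (−0.34). Of 25 YAP-TEAD targets, 4 rose and 16 fell (4 and 16 adjusted over the list alone, median −0.26, camera adjusted p = 2.34e-03, and adjusted p = 0.451 with an estimated correlation). NT5E fell by 1.96 ± 0.10, CCN2 by 1.62 ± 0.06 and AXL by 1.39 ± 0.04, and IGFBP3 (1.5), PTPN14 (0.52), CRIM1 (0.24) and GADD45B (0.19) rose.

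Of 24 glycolysis genes, 2 rose and 17 fell (2 and 17 adjusted over the list alone, median −0.26, camera adjusted p = 3.88e-03, and adjusted p = 0.520 with an estimated correlation). PFKP fell by 1.17 ± 0.04 and the lactate carrier SLC16A3 by 0.91 ± 0.06, and PFKFB4 and ALDOC rose by 0.63 and 0.29. Of 23 FOXO targets, 14 rose and 5 fell (14 and 5 adjusted over the list alone, median 0.30, camera adjusted p = 0.0188, and adjusted p = 0.520 with an estimated correlation). SESN3 rose from 18.2 to 123 CPM, PIK3IP1, an inhibitor of PI 3-kinase, by 1.59 ± 0.09 and PDK4 by 1.57 ± 0.08, and GADD45A, IRS2, KLF6, CITED2 and CAT fell. Of 22 fatty acid synthesis genes, 6 rose and 15 fell (6 and 15 adjusted over the list alone, median −0.38, camera adjusted p = 0.0483, and adjusted p = 0.604 with an estimated correlation). The desaturase SCD fell from 1991 to 435 CPM and ACLY by 1.42 ± 0.08. That call was lost without WT replicate 3 (adjusted p = 0.0504), E545K replicate 1 (0.0528), E545K replicate 2 (0.0509) or H1047R replicate 2 (0.0668), with library totals only (0.0552) and with the replicate block (0.0664).

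The other 13 lists were not called in H1047R against WT. Of 36 PI3K-AKT-mTOR components, 20 rose and 12 fell (21 and 12 adjusted over the list alone, camera adjusted p = 0.106). The lipid phosphatase INPP5D rose by 1.56 ± 0.04 and IRS1 by 2.57 ± 0.28 (3.39 without WT replicate 1), and AKT1 fell by 0.49 ± 0.04. Of 19 EGFR-family genes, 10 rose and 5 fell, as over the list alone (adjusted p = 0.200), with EPGN up by 1.92 ± 0.06 and EREG, NRG1, NRG2, BTC and RHBDF1 down, and a mean of −0.01 against a median of 0.19. Of 30 ATF4 response genes, 9 rose and 13 fell, as over the list alone (adjusted p = 0.375), and SLC7A5 fell from 5530 to 1449 CPM. AP-1 factors had 9 rises and 9 falls among 24 (10 and 9 adjusted over the list alone, adjusted p = 0.611, median −0.02, mean 0.10 and test upward). Basal genes had 10 and 12 among 29 (11 and 12 adjusted over the list alone, adjusted p = 0.637, median −0.01, mean 0.11 and test downward), with KRT16 up from 165 to 3299 CPM. Luminal genes had 11 and 12 among 32, as over the list alone (adjusted p = 0.760), with a median of −0.16 against an upward test. With upper-quartile scaling, the medians of the AP-1, ATF4 and basal lists lay above 0, at 0.04, 0.0037 and 0.04.

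Junction genes had 18 rises and 13 falls among 39 (18 and 14 adjusted over the list alone, adjusted p = 0.177), TGF-beta response genes 7 and 12 among 24, as over the list alone (adjusted p = 0.224), and histones 11 and 20 among 44, as over the list alone (adjusted p = 0.343). Hypoxia targets had 11 rises and 4 falls (P4HA1, LOX, PDK1 and SLC2A1) among 21, as over the list alone (adjusted p = 0.0599), and passed without H1047R replicate 3 (0.0383) and with upper-quartile scaling (0.0344). Matrix proteases had 8 and 17 among 28, as over the list alone (adjusted p = 0.0544), and passed without WT replicate 1 (0.05), H1047R replicate 1 (0.0164) or H1047R replicate 2 (0.0470), and with upper-quartile scaling (0.0386). Mitochondrially encoded mRNAs had 7 rises and 1 fall (MT-CO2) among 13, as over the list alone (adjusted p = 0.119), and passed without H1047R replicate 3 (7.14e-03). Ribosomal proteins had 6 and 16 among 54, as over the list alone (adjusted p = 0.139), and passed without H1047R replicate 1 (8.48e-04) and with library totals only (0.0375).

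The knock-in lines, both kept without EGF until the last 24 h, were also compared with each other. By camera, the squamous list was higher in H1047R, and the cell cycle, cholesterol synthesis, ERK-response and ATF4 lists were higher in E545K. With an estimated correlation these 5 had adjusted p = 0.218, 0.339, 0.489, 0.339 and 0.571. THBS1 (ENSG00000137801.11, chromosome 15, 39581079 to 39599466) was at 233 ± 2.0 CPM in E545K and 14.2 ± 2.23 in H1047R (SD, n = 3, −4.04 ± 0.09, adjusted p = 6.45e-14). The monooxygenase CYP4B1 was at 2.34 ± 0.228 and 91.9 ± 12.5 CPM (5.29 ± 0.10, adjusted p = 2.02e-14). ATF3 was lower by −3.33 ± 0.08 and AREG by −2.84 ± 0.13 in H1047R.

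Of 26412 genes, 14040 were called in H1047R against E545K, with 6841 higher and 7199 lower in H1047R, and at least 2-fold 2043 higher and 1913 lower. With library totals only, 33.2% of calls were higher against 48.7% with TMM (at least 2-fold, 40.9% against 51.6%), and the median of all genes moved from 0.02 to −0.12. On protein-coding genes alone 41.5% of the calls of at least 2-fold were higher, and without a low-count filter 44.9%. The depth, RNA makeup and table of the H1047R libraries differ here as well.

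Larger values in H1047R were those of CASP14 (5.46 ± 0.08), MUC16 (5.45 ± 0.18), S100A8 (5.35 ± 0.10), AZGP1 (6.19 ± 0.17), ATP13A4 (4.95 ± 0.13) and the protease inhibitor PI3 (5.41 ± 0.13). ANOS1 was at 5.66 CPM in WT, 0.0498 in E545K and 16.2 in H1047R (8.29 ± 0.19). Lower in H1047R were RYR1 (−9.43 ± 0.09), CCND2 (−6.19 ± 0.09), NR4A3 (−3.96 ± 0.11), FSIP1 (−3.74 ± 0.06), JAM3 (−3.42 ± 0.08) and MYH14 (−3.29 ± 0.23). CCND1 did not differ beyond the spread (−0.02 ± 0.07, adjusted p = 0.863), but was called without H1047R replicate 1 (−0.13, adjusted p = 0.0149). EGFR, MYC and AKT1 were lower (−0.48 ± 0.04, −0.58 ± 0.05 and −0.19 ± 0.04).

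Of 50 cell cycle genes, 1 (E2F2, 1.61 ± 0.13) was higher and 49 lower in H1047R (1 and 49 adjusted over the list alone), with a median of −1.75 (camera adjusted p = 2.96e-22, and adjusted p = 0.339 with an estimated correlation). RRM2 was at 22.4 CPM in E545K and 2.39 in H1047R. Of 39 squamous genes, 31 were higher and 1, KRT80, lower (31 and 1 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 2.64e-13, and adjusted p = 0.218 with an estimated correlation). Of 25 cholesterol synthesis genes, 1 was higher and 24 lower (1 and 24 adjusted over the list alone, median −1.24, camera adjusted p = 3.10e-10, and adjusted p = 0.489 with an estimated correlation). INSIG1 differed by −2.66 ± 0.12. Of 32 ERK-response genes, 2 (EPHA4 and SPRY1) were higher and 22 lower (2 and 22 adjusted over the list alone, median −0.49, camera adjusted p = 1.06e-05, and adjusted p = 0.339 with an estimated correlation). DUSP5 differed by −2.49 ± 0.06 and DUSP4 by −1.95 ± 0.09.

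Of 23 FOXO targets, 17 were higher and 4 lower (17 and 4 adjusted over the list alone, median 0.68, camera adjusted p = 1.20e-05, and adjusted p = 0.339 with an estimated correlation). TXNIP was at 124 CPM in E545K and 411 in H1047R and FBXO32 at 101 and 272, and GADD45A, KLF6, IRS2 and CAT were lower. Of 39 junction genes, 28 were higher and 5 lower (28 and 5 adjusted over the list alone, median 0.28, camera adjusted p = 5.55e-05, and adjusted p = 0.519 with an estimated correlation). CLDN1 was higher by 1.69 ± 0.06 and GRHL1 by 1.22 ± 0.07, and PKP2, OVOL2, ESRP2, JUP and CDS1 were lower. Of 30 ATF4 response genes, 6 were higher and 22 lower (6 and 22 adjusted over the list alone, median −0.51, camera adjusted p = 1.82e-04, and adjusted p = 0.571 with an estimated correlation), among them GARS1 (−1.51 ± 0.07) and PHGDH (−1.18 ± 0.04). Of 35 mesenchymal genes, 7 were higher and 18 lower (8 and 20 adjusted over the list alone, median −0.49, camera adjusted p = 2.74e-03, and adjusted p = 0.481 with an estimated correlation), with FN1 at −2.38 ± 0.08 and VIM at −2.02 ± 0.06.

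Of 21 hypoxia targets, 14 were higher and 4 lower (14 and 4 adjusted over the list alone, median 0.33, camera adjusted p = 4.09e-03, and adjusted p = 0.339 with an estimated correlation). ADM was higher by 1.83 ± 0.07 and EGLN3 by 1.30 ± 0.13, and ANGPTL4, P4HA1, P4HA2 and PDK1 were lower. Of 24 glycolysis genes, 3 (SLC2A3, PFKFB4 and SLC2A1) were higher and 16 lower (3 and 16 adjusted over the list alone, median −0.23, camera adjusted p = 5.44e-03, and adjusted p = 0.520 with an estimated correlation). Of 36 PI3K-AKT-mTOR components, 19 were higher and 8 lower (19 and 9 adjusted over the list alone, median 0.16, camera adjusted p = 9.92e-03, and adjusted p = 0.489 with an estimated correlation). IRS1 differed by 1.18 ± 0.26, GAB2 by 1.01 ± 0.08 and FOXO3 by 0.97 ± 0.04, and the list's call was lost with library totals only (adjusted p = 0.0851). Of 47 interferon genes, 23 were higher and 8 lower (24 and 10 adjusted over the list alone, median 0.18, camera adjusted p = 0.0122, and adjusted p = 0.604 with an estimated correlation), with IFI44L at 1.62 ± 0.12. Of 22 fatty acid synthesis genes, 5 (ELOVL5, SCD5, ACSL1, LPIN1 and GPAM) were higher and 14 lower (5 and 14 adjusted over the list alone, median −0.29, camera adjusted p = 0.0310, and adjusted p = 0.571 with an estimated correlation), with SCD at −2.21 ± 0.15.

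The other 12 lists were not called between the knock-in lines. EGFR-family genes had 5 higher (ERBB3, EPGN, ERBB2, LRIG1 and TGFA) and 10 lower among 19 (5 and 11 adjusted over the list alone, camera adjusted p = 0.101), and NRG1 differed by −2.87 ± 0.14. NF-kB genes had 15 and 12 among 31, as over the list alone (adjusted p = 0.191), with SAA2 at 4.21 ± 0.13 and IL1B at −3.23 ± 0.08. TGF-beta response genes had 6 and 13 among 24, as over the list alone (adjusted p = 0.0615), with ID1 at −1.12 ± 0.07, and passed without E545K replicate 3 (0.0493) or H1047R replicate 2 (0.0429). Luminal genes had 13 and 11 among 32 (13 and 12 adjusted over the list alone, adjusted p = 0.485), with a median of 0.10 against a mean of −0.18. AP-1 factors had 9 and 13 among 24, as over the list alone (adjusted p = 0.419), p53 targets 11 and 5 (PLK3, AEN, BAX, GDF15 and SPATA18) among 24, as over the list alone (adjusted p = 0.174), and basal genes 12 and 10 among 29 (14 and 11 adjusted over the list alone, adjusted p = 0.572). With library totals only, the medians of the p53, basal, luminal and ribosomal lists lay below 0, at −0.06, −0.12, −0.04 and −0.06.

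Matrix proteases had 8 higher and 13 lower among 28, as over the list alone (adjusted p = 0.282), YAP-TEAD targets 7 and 11 among 25 (7 and 12 adjusted over the list alone, adjusted p = 0.188), and histones 14 and 21 among 44 (14 and 22 adjusted over the list alone, adjusted p = 0.419). Mitochondrially encoded mRNAs had 7 higher and 1 lower (MT-CO2) among 13, as over the list alone (adjusted p = 0.101), and passed without H1047R replicate 3 (6.12e-03). Ribosomal proteins had 16 higher and 3 lower (RPSA, RPS4X and RPS7) among 54, as over the list alone (adjusted p = 0.0706), and passed without H1047R replicate 2 (0.0371) or H1047R replicate 3 (6.89e-04), and with upper-quartile scaling (5.10e-03).

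The calls of the knock-in lines against WT were set beside each other. Of 7296 genes called in both, 2745 were higher in both and 3181 lower in both, where independent lists would give 1278 and 1404. In opposite directions, 707 were higher in E545K and lower in H1047R and 663 the reverse, where independent lists would give 1310 and 1369. At least 2-fold in both, 699 of 1089 genes were higher in both and 335 lower in both, where independent lists would give 119.8 and 50.4. CLDN1 and POF1B (4.19 ± 0.12 and 4.44 ± 0.12) were higher in both, and VIM, AKAP12 and EEF1A2 lower in both. RND3 (1.36 ± 0.04 and −1.13 ± 0.04), ANLN (1.03 ± 0.06 and −2.02 ± 0.06) and THBS1 rose in E545K and fell in H1047R, and complement C3 (−1.10 ± 0.04 and 1.71 ± 0.04) and CXCL14 (−1.43 ± 0.07 and 2.57 ± 0.06) did the reverse. ANLN lies in the part of chromosome 7 described with the chromosomes.

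Both comparisons share the WT libraries. Across all genes tested 65.3% of fold changes had the same sign, and unchanged groups simulated against those libraries gave 67.7%. Pearson's r across genes was 0.486, against a mean of 0.558 (0.535 to 0.589) in the 20 simulations, and the covariance was 0.444 against 0.0765, a difference of 0.367. Genes are not independent replicates, and the 3 WT libraries cannot be split into parts of 2. The simulations called 0 genes in both by edgeR, and their highest covariance was 0.0848. They gave WT the pooled coefficient of variation (0.118, against 0.0328 within WT) and may overstate what the shared libraries add. The covariance therefore argues against noise of the shared WT libraries as its only source. The same-sign share and r do not decide this, because a shared control raises both in unchanged groups of like noise, even where that noise is small. A trait of WT itself, such as its culture with EGF, enters both comparisons and was not separated from genotype.

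**Figure D3:**
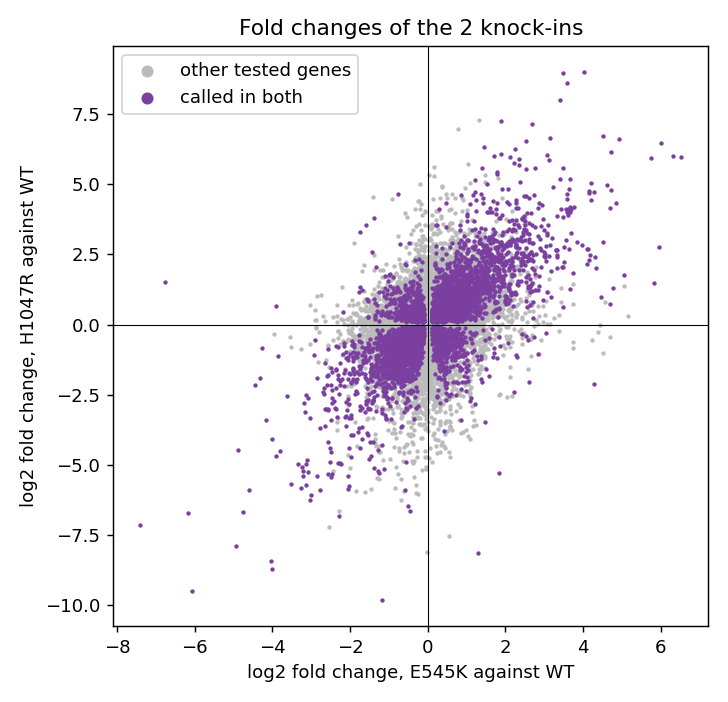
Log2 fold change in E545K against WT (x axis) and in H1047R against WT (y axis) for 26165 genes above 3 counts in every group, with 1 point per gene and genes called in both in purple. Of all 7296 genes called in both, 81.2% changed in the same direction.

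Markers of other cell types were low for the most part. Median levels of fibroblast markers were 0.141, 0.269 and 0.275 CPM of total counts in WT, E545K and H1047R, of leukocyte markers 0.055, 0.0377 and 0.0174, of endothelial markers 0.0784, 0.0978 and 0.035, and of adipocyte and erythroid markers 0.0662, 0.0644 and 0.0272. Single members were higher, among them COL1A1 (46.9, 62.7 and 64.0 CPM), CSF1R (33.6, 48.4 and 76.2) and KDR (8.56, 11.3 and 21.6). DCN went from 46.4 to 8.17 and 12.6 CPM, while FAP was at 26.1, 49.8 and 26.7. CDKN2A and CDKN2B, which are deleted in MCF-10A, were at 0.0495 and 0.0475 CPM in WT, 0.0249 and 0.0324 in E545K and 0 counts in H1047R.

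Fold changes were also described by position. The 801 genes of chromosome 7 had a median of 0.10 in E545K against WT (adjusted permutation p = 9.9e-04). That value came from the smallest p that 10000 permutations allow, 1e-04. Chromosomes 4 (median 0.068), 17 (−0.073) and 19 (−0.093) had the same adjusted p. Fold changes in E545K against WT fell with GC content (Spearman correlation −0.225, and 0.0168 after the correction for GC content and length). Under this correction, 29 medians over all comparisons moved beyond the spread between libraries and 43 did not. These were the medians of chromosomes and of 0 to 60 Mb of chromosome 7. A trend with GC content therefore stays open as a source of the medians of chromosomes 4, 17 and 19. The median of chromosome 7 came from the 276 genes at 0 to 60 Mb, a range chosen after the windows were seen, with a median of 0.76 (quartiles 0.52 and 0.98) and 93.5% above 0, while the 525 genes of the rest of the chromosome had a median of −0.06. The same 276 genes had medians of 0.10 in H1047R against WT and −0.68 in H1047R against E545K. EGFR (ENSG00000146648.18, 55019017 to 55211628) lies in this range. So do ANLN, GARS1 and IGFBP3, which were higher in E545K than in WT, and INHBA, which was lower. Along 0 to 50 Mb of chromosome 5, the windows at 0, 10, 30 and 40 Mb had medians of −0.31, −0.27, −0.20 and −0.23 in E545K against WT (adjusted permutation p = 3.2e-03, 0.0159, 0.0186 and 0.0221 over 759 window tests). In H1047R against WT they were −0.49, −0.50, −0.34 and −0.47 (adjusted permutation p = 3.2e-03, 8.2e-03, 0.0276 and 5.2e-03). Windows of other chromosomes also had an adjusted p under 0.05 in each comparison.

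**Figure D4:**
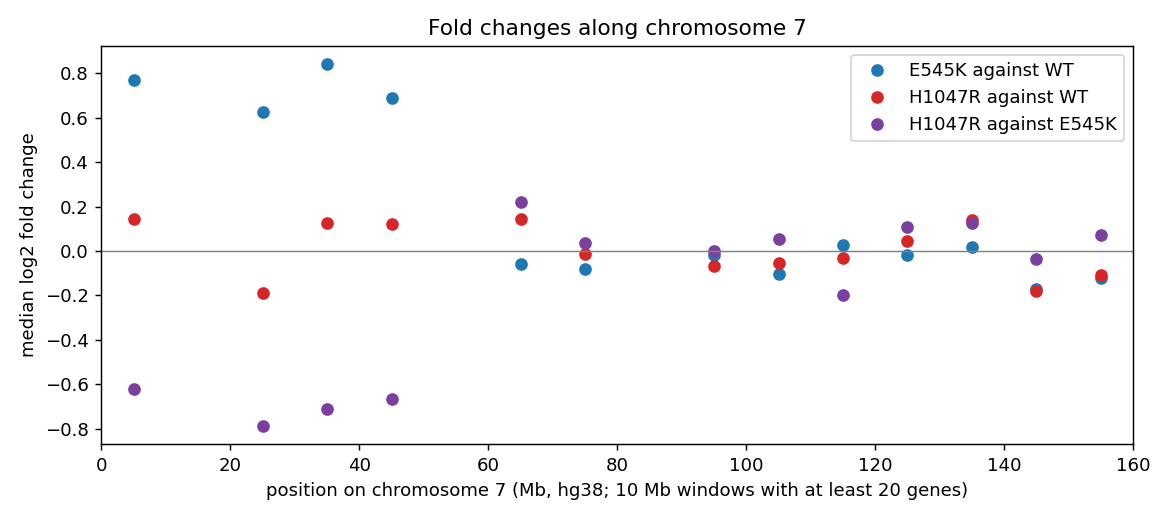
Median log2 fold change of genes in 10 Mb windows along chromosome 7 (hg38, windows with at least 20 genes), with 1 point per window and comparison. Windows between 0 and 60 Mb lie above 0 in E545K against WT and below 0 in H1047R against E545K, and the 276 genes there have medians of 0.76 and −0.68.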

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

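The tests of chance placement and of a copy gain on chromosome 7 and the count of other genotypes in the H1047R table were chosen only after the result was seen, as were the corrections for GC content and length, depth and gene class that gave the calls kept.

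The knock-in lines changed in opposite directions against WT for 45 of 245 named genes, and 15 of these changed at least 2-fold in both lines. The rule for named genes took some because of their directions, so these numbers do not describe all genes, of which 37 and 18 of 1089 called at least 2-fold in both lines were opposite. For the 15 genes the choice itself fixed the sign and a size of over 2 log2 units of the difference, H1047R against E545K, so its test adds nothing and only values are given. The same holds for the sign of the cell cycle list, also taken because it changed in opposite directions, whose median difference was −1.75. Higher in E545K and lower in H1047R than in WT were ANLN (difference −3.05), FSIP1 (−3.74), H2BC14 (−3.47), JAM3 (−3.42), NDC80 (−2.04), RND3 (−2.49), RYR1 (−9.43), THBS1 (−4.04) and its antisense neighbour THBS1-AS1 (−3.78), which shares 88.2% of its exon bases. Lower in E545K and higher in H1047R were ANOS1 (8.29), C3 (2.82), CXCL14 (4.0), LCN2 (3.37), OLFML3 (5.18) and PLA2G2A (5.12). ANLN lies at 0 to 60 Mb of chromosome 7, where most genes were higher in E545K than in WT.

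Genes at 0 to 60 Mb of chromosome 7 were higher in E545K than in WT, with medians of 0.75, 0.75 and 0.76 in the 3 E545K libraries and 0.12, 0.11 and 0.05 in the 3 H1047R libraries. Placing genes at random gave a 10 Mb window as high in a share of 0.0001, the smallest that 10000 permutations can give, which argues against chance placement. A correction for GC content and gene length left the median at 0.756, which argues against that bias. A gain of this region in the E545K line is a candidate explanation, since 93.5% of the 276 genes lay above 0 and the rest of the chromosome had a median of −0.06. It remains a hypothesis, because the region was found in the same data and no DNA was analysed here.

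The H1047R libraries stood apart from both other groups in depth, RNA makeup and expression. Of the calls of at least 2-fold against WT, 89.3% were kept after H1047R was thinned to the depth of the other groups, and 93.2% after the correction for GC content and length. On protein-coding genes alone, 96.2% of the protein-coding calls were kept. The number of counts, a trend with GC content and length, and the scaling by other gene classes thus do not account for most of the calls. Thinning leaves the expected fold changes as they were, and the protein-coding fit changes them only through the scaling. An effect of RNA makeup beyond scaling therefore stays open. A difference in preparation or sequencing cannot be told apart from the genotype, because 0 libraries of another genotype stand in the H1047R table. The genotype itself stays open as untested.

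Random lists matched on GC content, length and expression had medians of −0.17 to 0.11 against −1.38 for the cell cycle list in H1047R against WT, and −0.21 to 0.20 against 3.24 for the squamous list, with a permutation p of 0.0001 for each, the smallest that 10000 draws can give. The draws took genes as independent. The estimated correlation between members was 0.433 for the cell cycle list and 0.105 for the squamous list, so these p-values may be too small. The squamous test was run again on all 39 members after a first run had kept only members of at least 1 CPM. With 6 libraries, the 1 split of 10 that gave as many calls as the real one was the real one itself in each comparison, and 10 splits are too few for a share under 0.05. The real splits gave 12585, 14049 and 13012 edgeR calls in E545K against WT, H1047R against WT and H1047R against E545K. The highest of the others gave 0 calls by edgeR, with 210 to 305, 100 to 579 and 99 to 518 genes at an unadjusted p under 0.05. Each other split mixes the genotypes, which puts their difference into the spread within groups, so these low numbers decide nothing.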

How the results depend on the processing

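Alternatives chosen only after the result was seen were the correction for GC content and length, thinned H1047R libraries, protein-coding genes only, the fit without genes at 0 to 60 Mb of chromosome 7, and upper-quartile scaling of the lists. Over the alternatives run, named genes kept their direction and side of the threshold in 4539 of the refitted values, lost their call in 64, gained it in 1 and reversed in 7. For gene lists these numbers were 1021, 51, 41 and 12. Of the counts of calls, 160 stayed within 1.5 times the first value and 12 did not. Medians of chromosomes and of 0 to 60 Mb of chromosome 7 moved beyond the spread between libraries in 59 and stayed within it in 229.

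With an estimated correlation 0 list tests passed, and by fry 56 did, against 36. With at least 1 CPM in 3 libraries, fewer genes were tested and 987, 2212 and 1743 were called at least 2-fold in E545K against WT, H1047R against WT and H1047R against E545K. On protein-coding genes only there were 1114, 2608 and 2188, again from fewer genes tested. Testing against a log2 fold change of 0.5, a stricter question, gave 1998, 5602 and 4599 calls. Of the genes called in both knock-in lines, 1089 were at least 2-fold in both. DESeq2 gave 10004, 14926 and 14306 calls, limma-voom 7429, 13653 and 13232, and no low-count filter 9586, 16140 and 15295.

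Values that reversed were none of them past the threshold under the alternative, and the cause was not tested. By fry the direction turned for PI3K-AKT-mTOR components (adjusted p = 0.940) and fatty acid synthesis (0.959) in E545K against WT and for basal genes in H1047R against WT (0.737). Luminal genes turned in E545K against WT with upper-quartile factors (0.922) and library totals only (0.739). CCND1 in H1047R against E545K was at 0.0060 with at least 1 CPM in 3 libraries.

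Leaving out 1 library at a time gave 7979 to 11251 calls in E545K against WT, 13077 to 15791 in H1047R against WT and 12452 to 15295 in H1047R against E545K, and at least 2-fold 1676 to 2052, 4241 to 5182 and 3657 to 4536. The overlap was 5884 to 8589 and 34 to 39 list tests passed. Luminal genes had adjusted p from 0.763 to 0.999 in E545K against WT, turning without WT replicate 2 or 3, E545K replicate 3 or H1047R replicate 1 or 3. In H1047R against WT they had 0.497 to 0.982, turning without WT replicate 2 or H1047R replicate 1. The fold change of PREX1, E545K against WT, ranged from −2.79 to 0.11, the latter without WT replicate 1. CCND1 in H1047R against E545K ranged from −0.13 without H1047R replicate 1 to 0.062 without H1047R replicate 3, and also turned without E545K replicate 3 or H1047R replicate 2. ONECUT3 in H1047R against E545K, near the floor in both, ranged from −0.24 without E545K replicate 1 to 1.01, and EGFR in H1047R against WT from −0.0063 without H1047R replicate 3 to 0.032.

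The labels number replicates 1 to 3 in each group, but deviations of same-numbered libraries correlated at −0.0707 to 0.087, so the numbers were not taken as pairs. With the replicate block, 9441, 14394 and 13731 genes were called, the overlap was 7092 and 34 list tests passed. The block ended the calls of PIK3CA in H1047R against WT (adjusted p = 0.0653), THRSP in E545K against WT (0.0640), PREX1 in E545K against WT (0.0617) and PHLDA3 in E545K against WT (0.0503), and of the mesenchymal list in E545K against WT (0.0598) and the fatty acid list in H1047R against WT (0.0664). Depth limits low genes, since 3 counts are 0.0220 to 0.0316 CPM in WT and E545K libraries.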

Other observations

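The test of estrogen-induced genes in WT replicate 1 was chosen only after the result was seen.

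Further members of the fixed lists, whose groups are described in the report, differed between the knock-in lines. The matrix protein gene TGFBI was at 8472 CPM in WT, 5007 in E545K and 2438 in H1047R (H1047R against E545K −1.04 ± 0.04). The laminin gene LAMB3 was at 678, 1096 and 388 CPM (−1.50 ± 0.04). The desaturase FADS1 was at 70.9, 91.1 and 27.3 CPM (−1.74 ± 0.10), and the lipoprotein receptor VLDLR at 1.57, 3.06 and 11.4 CPM (1.89 ± 0.08). At 140 to 150 Mb of chromosome 5, which holds the protocadherin-alpha genes, the median was 0.30 in E545K against WT, 0.70 in H1047R against WT and 0.30 in H1047R against E545K (adjusted permutation p = 3.2e-03 in each). Protocadherin-alpha genes share exon bases and so reads, while the permutation took each gene as independent. These p-values may therefore be too small.

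WT replicate 1 held 8 genes that were at least 20 counts and more than 5 times above the highest other library plus 0.05 CPM, and the 8 other libraries held 0 such genes each. They were TFF1 (9.93 CPM of total counts), IGFBP5 (8.99), PREX1 (8.60), NPY1R (7.78), GFRA1 (2.71), TSPYL5 (1.23) and 2 genes without symbols. RNA of an estrogen receptor-positive luminal breast cancer line in this library is a candidate source. Of 28 listed other markers of such lines, 15 with a mean under 1 CPM over WT replicates 2 and 3 were tested. Their median log2 ratio over that mean was 0.86 (random lists −0.35 to 0.24, permutation p = 0.0001, the smallest that 10000 draws can give). Of these 15, 12 lay above both other WT libraries, though only 6 above all other libraries. The median is the value of PKIB, at 1.72 CPM in WT replicate 1 and 2.75, 2.88 and 3.06 in H1047R. An estrogen response of this culture stays open. The median log2 ratio of 15 estrogen-induced genes of at least 5 CPM in WT replicates 2 and 3 was 0.0057, but that limit left out 4 genes of lower level, which all lay above both other WT libraries, so the test decides nothing. PKIB and CXCL12, among these 4, are also among the 15 markers of such lines, so both explanations draw on them. The pattern was noticed in the leave-one-out results and a first scan with a smaller added constant gave more genes than the 8, the route by which such RNA might enter was not tested, and no other biological explanation was tested.

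Calls of named genes lost without this library in E545K against WT were TFF1 (−0.40 without it, adjusted p = 0.520), PRLR (−0.56, 0.249), PREX1 (0.11, 0.893), CLDN3 (−1.36, 0.1), ENO2 (−0.73, 0.110), CA9 (−1.25, 0.0897), THRSP (1.69, 0.107) and PHLDA3 (−0.13, 0.0686), and in H1047R against WT BMP7 (−1.49, 0.216). The first 3 changes rested on this library, since they were −3.01, −2.32 and −2.31 with all libraries and still at or below −2.94, −2.16 and −2.15 without any single other one. Their calls were also lost without some other libraries, at about the same fold change: TFF1 without any 1 of the E545K libraries, PREX1 without any 1 of these or H1047R replicate 2, and PRLR without E545K replicate 1. CLDN3 (−2.21 with all libraries) lost its call only without this library. CA9, THRSP and PHLDA3 kept about their fold change (−1.30, 1.63 and −0.12 with all libraries) and also lost their calls without several other libraries. ENO2 (−1.04) also lost its call without E545K replicate 2, and BMP7 (−2.30) without H1047R replicate 2.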
